A study of Mus musculus with 6 samples.

How the data were processed

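The 6 arrays held 3 IP and 3 unbound samples, each from a pool of 5 mice, with 20 ng of total RNA put through the Affymetrix two-cycle amplification, per the labels' protocols. The deposited log2 values, 45101 per array, were made by the authors with GCRMA (background correction, quantile normalisation and summary per probe set), applied to the replicates of each group separately, per the submitters' processing notes. Its version is not given in the sources used here. That the values are on a log2 scale was read from the deposited values: each group has its own floor, 2.22 for IP and 2.17 for unbound arrays. Array medians were 2.42 to 2.43 in IP and 3.20 to 3.23 in unbound RNA. The separate normalisation leaves the level of one group against the other open. The same 3 values on every array of a group were found for 15.8% of IP and 0.481% of unbound probe sets with a mean of 5 or more, and the median SD of tested genes was 0.11 in IP and 0.18 in unbound RNA.

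Following the notes' recommendation, -0.23 was added to every IP value, the mean difference between groups over the 18 biotinylated hybridisation control probe sets. Genes were named from the platform's annotation. Of the probe sets, 34958 had 1 gene symbol, 932 had several, 9160 had none and 64 were controls. The Entrez IDs of 34754 probe sets were found in a RefSeq table of assembly GRCm38.p6, which changed 0 symbols and was used further only for genomic spans and the order of neighbouring genes. Only probe sets with 1 symbol were used, covering 18193 genes, each read by its brightest probe set over all 6 arrays. A gene was tested where at least 3 of 6 arrays reached a log2 value of 5, here called the detection limit. The filter was applied after scaling, so the members of a list that were tested can differ between scalings. A gene below the limit on every array of 1 group was therefore tested only if all 3 arrays of the other reached it. The filter thus fixed the direction of such genes. The test was limma's lmFit and eBayes (limma 3.58.1, R 4.3.3) on group alone, two-sided, with Benjamini-Hochberg adjustment over the 10581 genes tested. A gene was called, and is described as having risen or fallen, where its adjusted p was under 0.05 and its change at least 2-fold. Folds given as at least a value set the bright group's mean against the dim group's mean, with each dim array counted at no less than the limit of 5. The samples of a group are biological replicates, per the labels.

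Each unbound sample's label names the replicate it belongs to, so numbers were checked for pairing: deviations from the group means of IP and unbound samples of the same number correlated at 0.27, 0.16 and 0.10 across genes, all over the preset bound of 0.1, the third only just, and IP replicate 3 correlated more with unbound replicate 2 (0.21). By the rule fixed beforehand the numbers pair the samples, though such low correlations do not establish it. Values below come from the unblocked fit unless a block is named, and a fit with the pairs as a block was run beside it.

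Genes were named by a rule fixed before the data were examined: Slc6a4, the CELF family, every measured gene of serotonin synthesis, storage and uptake, the 10 largest increases and 10 largest decreases among called genes without overlap between groups, and up to 3 called members of each list with the largest change, or 2 members of a list with none called. Other members of a list are given where a count had to be made specific, chosen after their values were seen. Of the 107 genes so named, 105 were tested. Among the 31 named genes with over 1 tested probe set, 1 (Celf4) had a probe set of the opposite sign. Slc22a3 and Fev had no probe set with a single symbol and were not analysed here.

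The 29 gene lists were also fixed beforehand: serotonin synthesis, storage and uptake, serotonergic transcription factors, serotonin receptors, the CELF family, other neuronal RNA-binding proteins, autism-associated genes, catecholaminergic, cholinergic, GABAergic and glycinergic, and glutamatergic neurons, pan-neuronal genes, neuropeptides, peptide processing and dense-core granules, receptors on serotonergic neurons, astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia and macrophages, endothelial cells, pericytes and smooth muscle, ependymal and choroid plexus cells, red blood cells, cerebellar granule and Purkinje cells, immediate early genes, neighbours of Slc6a4, ribosomal proteins, oxidative phosphorylation, potassium channels and Hox genes. Of their 423 tested genes, 12 were on over 1 list. Lists were tested with camera against all other genes at a preset correlation of 0.01, two-sided, adjusted over the 28 lists with at least 3 tested members. Camera with an estimated correlation and fry were run beside it. Span-matched comparisons drew 10000 random lists matched on genomic span and mean level.

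The alternatives tried were other scalings between groups (none, array medians, quantile normalisation, each array by its own biotin controls), the pairs as a block, no filter or a filter at log2 7, the mean of all probe sets or every probe set by itself, no fold threshold or at least 4-fold, eBayes with trend and robust options, and each array or pair left out in turn. Scaling by the poly-A spike controls, by the median over expressed probe sets, a spread from the unbound arrays alone, and leaving out genes with identical replicate values were added after the data had been seen. Simulated arrays had 100 genes changed by each fold, drawn from genes with a mean log2 value of 7 or more, with every probe set of a changed gene changed. The comparison of IP with unbound recovered 89% of 3-fold and 99% of 8-fold changes among 9750 genes. It called 1 of the 9550 other genes, a few of which had been given a smaller shift. Both groups were drawn from the same means and SDs with a constant offset. The simulation therefore does not test the separate normalisation, identical replicate values or dimmer genes. Figures were drawn with Python 3.11.15, matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.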

Results

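RNA was measured on Affymetrix mouse expression arrays after translating ribosome affinity purification (TRAP), in which tagged ribosomes and the mRNA bound to them are pulled out of a tissue lysate. The mice carried a bacterial artificial chromosome transgene of the Slc6a4 JD60 line, in which the Slc6a4 (serotonin transporter) regulatory region targets serotonin neurons. Midbrain and brainstem without cerebellum were taken from adult males and females aged 6 to 12 weeks, with 5 mice pooled per sample. The IP group held 3 samples of immunoprecipitated, ribosome-bound RNA from serotonin neurons, and the unbound group held 3 samples of the RNA left in the lysate, which stands for the whole tissue. Each of the 6 arrays gave 45101 log2 values. Pearson's r across probe sets was 0.996 to 0.999 between IP arrays, 0.994 to 0.997 between unbound arrays and 0.924 to 0.932 between an IP and an unbound array. The number of arrays limits the precision of every value below.

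The comparison of IP with unbound RNA asks which mRNAs are enriched on the ribosomes of serotonin neurons relative to the RNA left in the lysate. The groups differ both in cell type and in whether the RNA was ribosome-bound, and the design cannot tell these apart. The serotonin transporter gene Slc6a4 itself was 35.5-fold higher in IP, with log2 expression of 14.20 ± 0.12 (SD, n = 3) in IP and 9.05 ± 0.07 (SD, n = 3) in unbound RNA (limma, log2 change 5.15 ± 0.09 SE, adjusted p = 3.73e-07). Genes tied to the synthesis of serotonin and its cofactor rose with it, among them Tph2, Ddc, Gch1 and Gchfr. The vesicular transporter gene Slc18a2 and both monoamine oxidase genes rose too. Celf6, the RNA-binding protein gene that the study is named for, was 7.13-fold higher in IP. Most tested transcripts of astrocytes, oligodendrocytes and microglia fell, as did most of those of catecholaminergic and GABAergic neurons.

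Of 10581 genes tested, 1104 (10.4%) were higher in IP and 4354 (41.1%) were lower, by at least 2-fold at an adjusted p under 0.05. Lower genes made up 79.8% of all calls after the IP arrays had been scaled to the biotin hybridisation controls. That share depends on the scaling between the separately normalised groups. It was 71.4% without scaling, 49.7% (2507 higher and 2479 lower) after quantile normalisation over all 6 arrays, 46.2% (2887 and 2481) with each array centred on its median over expressed probe sets, and 36.7% (3563 and 2067) with each array centred on its median over all probe sets. The median log2 change of tested genes moved with it, from -0.65 under the biotin scaling to -0.41 unscaled, 0.04, 0.20 and 0.44 in the same order. The median over all probe sets lay under the detection limit on every array (2.42 to 3.23), so centring on it aligns dim values. Directions that turn only under that scaling, here and below, carry this limit. All 1104 genes higher under the biotin scaling were also higher without scaling and under both median scalings, and 1057 of them were higher under quantile normalisation. A scaling to the poly-A spike controls, chosen after the data had been seen, made nearly every gene lower (35 higher and 9992 lower, median log2 change -3.37), and 624 of the 1104 higher genes were then called lower. The IP and unbound values of 83.0% of tested genes did not overlap (2533 higher and 6249 lower in IP), where chance gives 10% for 3 exchangeable arrays against 3, a condition that normalising the groups separately does not meet.

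**Figure D1:**
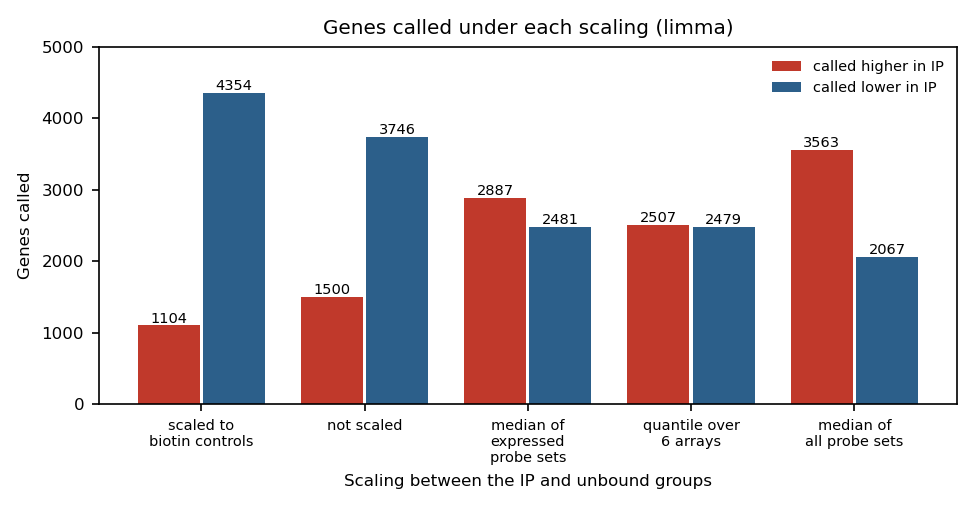
Number of genes called higher (red) and lower (blue) in IP than in unbound RNA under 5 ways of scaling the 2 groups of 3 arrays to each other. Lower genes outnumber higher genes with the biotin controls (4354 against 1104) and without scaling (3746 against 1500), and higher genes outnumber lower genes with either median.

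Genes of serotonin synthesis, storage and uptake had the highest median of the lists. Gchfr rose by 7.17 on the log2 scale (144-fold, adjusted p = 3.62e-07), Gch1 by 6.18 (72.3-fold, adjusted p = 4.71e-07), Tph2 by 5.81 (56.1-fold, adjusted p = 4.54e-07) and Slc18a2 by 5.80 (55.8-fold, adjusted p = 1.43e-06). Tph2 reached 15.16 ± 0.14 (SD, n = 3) in IP against 9.35 ± 0.17 (SD, n = 3) in unbound RNA. Maob rose by 4.27, Ddc by 4.14, Pts by 2.04 and Maoa by 1.12. Qdpr, which recycles the cofactor tetrahydrobiopterin, was abundant in both fractions (14.98 in IP, 15.21 unbound) and was not called at a log2 change of -0.24, a sign that turned positive with either median scaling. Tph1 had means below the detection limit in both groups, at 4.45 ± 0.63 in IP and 2.22 ± 0.08 in unbound RNA (SD, n = 3), and was not tested. In all, 9 of the 10 tested members were higher and none was lower (7 and 2 under the poly-A scaling), with a median log2 change of 4.71 (camera, adjusted p = 1.38e-07, and adjusted p = 0.273 with an estimated correlation).

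**Figure D2:**
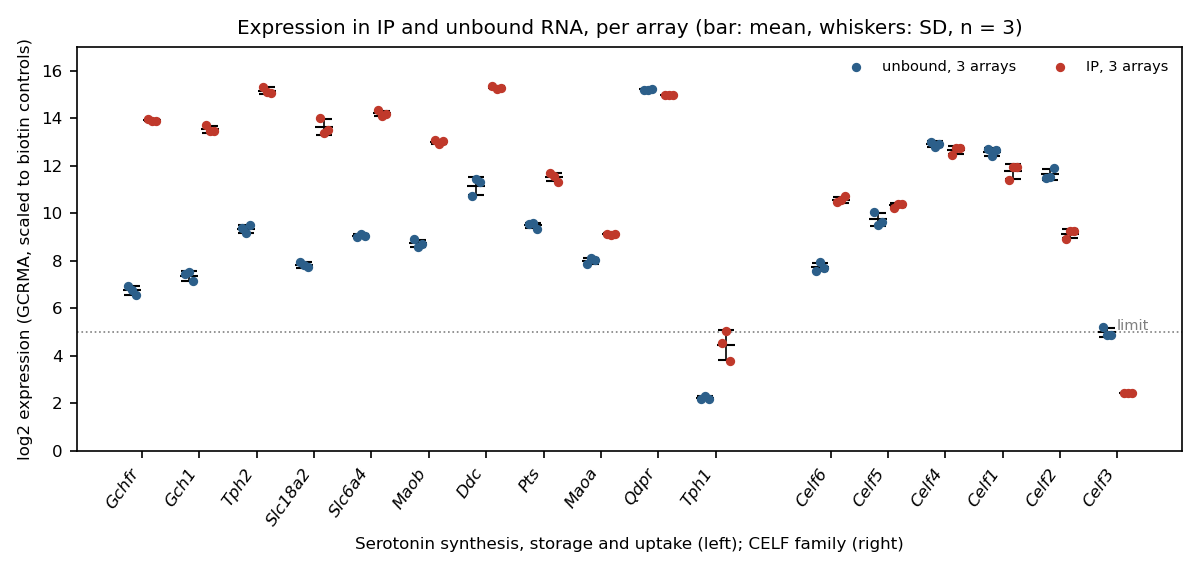
Log2 expression on each IP (red) and unbound (blue) array of the genes of serotonin synthesis, storage and uptake, ordered by log2 change, and of the CELF family; bars and whiskers give the mean and SD of 3 arrays, and the dotted line is the detection limit of 5. Gchfr stands at 13.92 in IP against 6.76 unbound and Celf6 at 10.58 against 7.74, while Qdpr and Celf4 lie close together.

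Celf6 was 10.58 ± 0.13 in IP and 7.74 ± 0.18 in unbound RNA (SD, n = 3), a log2 change of 2.83 ± 0.12 SE (limma, adjusted p = 4.88e-06), with all 3 IP arrays above all 3 unbound arrays. It was the only CELF member called higher under the biotin scaling, and it was not called under the poly-A scaling, at 0.16. Celf5 had a log2 change of 0.60, under the 2-fold limit, and was called higher under quantile normalisation (1.01) and both median scalings (1.62 and 1.40). Celf4 was at -0.26 and Celf1 at -0.83 (-1.75 and -1.14 by its other probe sets), neither of them called, and Celf2 was 5.65-fold lower in IP. Celf4 changed sign under both median scalings (0.77 over all probe sets and 0.55 over expressed ones) and Celf1 under the median over all probe sets (0.19). Another probe set of Celf4 had a log2 change of 0.32. Celf3 had means below the detection limit, at 4.99 in unbound RNA and 2.45 in IP, and was not tested. The CELF list had a median log2 change of -0.26 and a mean of -0.03, both negative, while camera placed it above other genes (adjusted p = 0.471, and adjusted p = 0.0320 under the poly-A scaling, where 0 members were higher and 4 lower).

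On the list of other neuronal RNA-binding proteins, 11 of 18 tested genes were lower, none was higher, and the median was -1.34 (camera, adjusted p = 0.175, a call gained with every probe set tested by itself). Every probe set then counts as a list member of its own, though probe sets of a gene are not independent. Camera calls gained that way, here and below, carry this limit. Members, Qk among them, may also be expressed in glia, so a fall need not concern neurons. Nova1 (-3.32), Qk (-2.89) and Mbnl2 (-2.51) fell most. With arrays centred on their median over all probe sets, 3 members were higher and 4 lower. Of 33 tested genes on a list of autism-associated genes, Slc6a4 and Oxtr were higher and 17 were lower (median -1.21, camera adjusted p = 0.376). Foxp2 (-4.03) fell and Grin2b was at least 2.80-fold lower. That balance turned to 7 higher and 6 lower with the median over all probe sets.

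Of 10 tested transcription factors of serotonin neurons, 5 rose: Gata2 by 4.69 and Gata3 by 2.64, with Lmx1b at least 7.72-fold, En1 at least 2.12-fold and Nkx6-1 at least 1.61-fold higher. Insm1, Nkx2-2 and Pou3f2 were lower. The list as a whole was called higher (median 0.81, camera adjusted p = 0.0390, and adjusted p = 0.281 with an estimated correlation), its camera call was lost without scaling, with quantile or median scaling and with the filter at log2 7, and 1 was higher and 5 lower under the poly-A scaling. Among serotonin receptors, Htr1d was 10.6-fold higher, with Htr1a, Htr1b and Htr5b, while Htr2c (-3.49) and Htr7 (-2.13) fell and Htr4 was at least 1.91-fold lower. That made 4 higher and 3 lower of 8 (0 and 5 under the poly-A scaling), with a median of 0.21, a mean of -0.07 and a camera direction of up (adjusted p = 0.280, and adjusted p = 0.00163 under the poly-A scaling).

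Receptors for other transmitters and peptides moved both ways. Hcrtr1, an orexin receptor, rose by 3.93 from 7.44 to 11.37, and Oxtr, Hrh1 and Npy2r rose with it. Crhr2, below the detection limit in unbound RNA, was at least 1.48-fold higher, and Crhr1, below it in IP, at least 1.75-fold lower, while Tacr3 fell by 1.14. The list had 5 higher and 2 lower of 9 (median 1.58, camera adjusted p = 0.00553, and adjusted p = 0.273 with an estimated correlation). The median over all probe sets, the filter at log2 7 and leaving out genes with identical values each ended that camera call, and the poly-A scaling left 1 higher and 5 lower. Genes of peptide processing and dense-core granules rose in 7 of 15 cases and fell in 2: Pcsk1 rose by 4.20 and Scg2 by 2.23, while Cadps2 fell by 3.01. Their median was 0.54 (camera, adjusted p = 0.00300, and adjusted p = 0.281 with an estimated correlation), quantile normalisation ended the call, and 1 was higher and 11 lower under the poly-A scaling. Among neuropeptides Trh, at least 44.8-fold higher in IP, was called with Tac1, Nmb and Pomc, while 10 of 18 were lower, including Nts, which was at least 9.27-fold lower, and Pmch. The neuropeptide median was -1.21 and the mean -0.59, whereas camera gave a direction of up (adjusted p = 0.811, a call gained under the poly-A scaling), and 8 were higher and 6 lower with the median over all probe sets.

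By estimated log2 change the first 10 increases were those of Wfdc12, 1700042O10Rik, Trh, Gchfr, Cited1, Klk1b27, Gpr4, Cryba2, Stmnd1 and Gch1. Wfdc12 was at least 30.4-fold higher in IP, Cited1 at least 25.6-fold and Gpr4 at least 34.6-fold. All of these but Gchfr and Gch1 had unbound means below the detection limit, so their order, and their place before Tph2 and Slc18a2, is not established. The first 10 decreases were those of Adamts20, Lpl, Dmp1, Mab21l1, Tfap2b, Notch2, Mdfic, Plce1, Jam2 and Adamts3. Adamts20 was at least 23.9-fold lower in IP and Lpl at least 18.0-fold, and all of these had IP means below the limit, which leaves their order open too. The dimmer group lay below the limit for 184 of the higher and 1411 of the lower genes, and the fold against the limit was under 2 for 76 and 423 of them. Among genes measured in both fractions, a selection made after their values were seen, Ctxn1 rose by 5.07, Irs4 by 4.01 and Gpx3 by 3.39, while Ecrg4 (-4.94) and Dnmt3a (-4.88) fell.

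Tested glial and vascular transcripts fell almost without exception. Of the genes on the array, 6 of 10 pericyte, 6 of 14 endothelial and 11 of 17 microglial and macrophage ones were tested. Every vascular gene named below lay under the detection limit on every IP array, so the filter fixed its direction. The same was true of Sox9, Acsbg1, Fgfr3, Olig2, Myrf, Vcan, Pdgfra, Cx3cr1, C1qa, Kcnj13, Ccdc153 and Clic6. Gfap, Mobp and Csf1r were measured in both fractions. All 20 astrocyte genes were lower (median -3.18, camera adjusted p = 2.95e-04, and adjusted p = 0.347 with an estimated correlation), with Sox9, Acsbg1 and Fgfr3 at least 6.82-fold, 4.10-fold and 11.1-fold lower, and Gfap fell by 4.48. All 17 oligodendrocyte genes were lower (median -3.37, camera adjusted p = 0.00150, and adjusted p = 0.401 with an estimated correlation), among them Olig2, Myrf and Mobp, and 8 of 9 oligodendrocyte precursor genes were lower (median -3.54, camera adjusted p = 0.0443, and adjusted p = 0.357 with an estimated correlation), among them Vcan, Olig2 and Pdgfra, with Cspg5 at 0.79 and not called. Of 11 genes of microglia and macrophages, 10 were lower (median -3.36, camera adjusted p = 0.0163, and adjusted p = 0.281 with an estimated correlation), among them Cx3cr1, Csf1r and C1qa, and Aif1, just below the detection limit in unbound RNA, was called higher at a bound of at least 1.66-fold. Pericyte and smooth muscle genes were lower in 6 of 6 cases (Abcc9, Vtn and Cspg4 among them, median -3.09, camera adjusted p = 0.0390, and adjusted p = 0.353 with an estimated correlation). Endothelial genes were also lower in 6 of 6 (Slco1c1, Ptprb and Slco1a4 among them, median -2.65, camera adjusted p = 0.0622, a call gained under every other scaling but the poly-A one and with every probe set by itself). Of the 6 ependymal and choroid plexus genes, Dynlrb2 was higher and 5 were lower (Kcnj13, Ccdc153 and Clic6 among them, median -3.34, camera adjusted p = 0.246, a call gained with the median over all probe sets and with each array's own biotin controls). The poly-A scaling ended the camera calls of astrocytes, oligodendrocytes, their precursors and pericytes, and testing without a filter ended those of oligodendrocytes, their precursors, microglia and pericytes. The filter at log2 7 ended the calls of precursors and pericytes, and the mean of probe sets and the removal of identical values those of precursors and microglia. No gene of the red blood cell list passed the detection limit. Glial mRNA was depleted but still measured in IP, with Mbp at 13.63 in IP and 15.30 in unbound RNA.

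Most tested genes of catecholaminergic, GABAergic and glutamatergic neurons were lower. None of the lists of other transmitter types passed camera in the comparison as fixed beforehand, though some passed under alternatives. Slc6a2, Aldh1a1 and Nr4a2 were among the 6 of 7 catecholaminergic genes that fell (median -3.28, camera adjusted p = 0.0622), as were Th and Slc6a3. This list was called without scaling, with the median over all probe sets, with each array's own biotin controls and with every probe set by itself. All 6 GABAergic and glycinergic genes were lower, among them Slc6a5, Tal1 and Pvalb (median -2.80, camera adjusted p = 0.0542, adjusted p = 0.0484 with the replicate pairs as a block, and adjusted p = 0.401 with an estimated correlation), and the list was also called under every other scaling but the poly-A one and with every probe set by itself. Lhx9, Tcf7l2 and Slc17a6 were the 3 lower genes of 4 glutamatergic ones (median -3.73, camera adjusted p = 0.175, a call gained with the median over all probe sets, each array's own biotin controls and every probe set by itself). Isl1 was the lower gene of 3 cholinergic ones, with Prph at -0.10 and Ret at 0.08 (median -0.10, mean -1.47, camera direction down though the median lay 0.55 above that of all genes, adjusted p = 0.831), and the list median turned positive without scaling, under quantile normalisation and under both median scalings. Cerebellar granule and Purkinje cell genes fell in 7 of 9 cases, among them Zic1, Cbln3 and Car8 (median -3.33, camera adjusted p = 0.0443, and adjusted p = 0.510 with an estimated correlation), a call lost with the poly-A scaling, either changed filter, the mean of probe sets and the removal of identical values. Cerebellum was not part of the tissue, so these falls need not concern cerebellar cells. Pvalb is also on the GABAergic list. All 6 tested Hox genes, of 33 on the array, were lower, among them Hoxc5, at least 7.67-fold, Hoxb4 and Hoxb5 (median -2.68, camera adjusted p = 0.0542). Camera gave adjusted p = 0.0484 with the pairs as a block and adjusted p = 0.281 with an estimated correlation. The same alternatives as for the GABAergic list, and testing without a filter, gained this list a call. Without the filter the Hox median relative to all genes was only -0.31, against -2.03 with it. Hoxc5 and Hoxb4 lay below the limit on every IP array, so the filter fixed their direction. That was also true of Slc6a2, Tal1, Lhx9, Isl1, Cbln3 and Arc. Immediate early genes were lower in 4 of 6 cases, among them Arc, Egr1 and Nr4a1 (median -1.57, camera adjusted p = 0.0876). Under quantile normalisation 9 members passed the filter, with 3 higher and 2 lower. Nr4a1 (-1.77) lost its call with quantile normalisation (-0.62) and with the median over all (-0.75) or expressed probe sets (-0.97).

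Of 19 pan-neuronal genes, Uchl1, Tubb3 and Gap43 were higher and 5 were lower, including Nefm, Map2 and Nefh (median -0.57, camera direction up, adjusted p = 0.605). Their median turned positive with either median scaling, with 7 higher and 3 lower for that over all probe sets. Under the poly-A scaling 0 were higher and 18 lower. Potassium channel genes were lower in 31 of 50 cases and higher in 4 (median -1.25, camera adjusted p = 0.0443, and adjusted p = 0.510 with an estimated correlation). Kcnj13, Kcnj16 and Kcne2, all below the detection limit in IP, were at least 6.47-fold, 4.79-fold and 2.46-fold lower, while Hcn3 rose by 2.69 and Kcna5 by 2.10. The balance was 8 higher and 15 lower with the median over all probe sets, 7 and 17 with quantile normalisation and 0 and 47 with the poly-A scaling. The camera call was lost with quantile normalisation, the poly-A scaling, either changed filter, the mean of probe sets and the removal of identical values. The channel median lay at the 27.2th percentile of random lists matched on genomic span and mean level.

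Ribosomal protein genes were higher in 18 of 45 cases and lower in none (median 0.89, camera adjusted p = 1.58e-16, and adjusted p = 0.273 with an estimated correlation). With either median scaling 44 were higher and 0 lower, and under the poly-A scaling 0 were higher and 38 lower. Rps27 was at least 4.43-fold higher, and Rps10 rose by 2.20 and Rpl19 by 1.87. The list's median lay at the 95.5th percentile of random lists matched on span and level, whose own median was 0.57. Oxidative phosphorylation genes were higher in 20 of 75 cases (median 0.44, camera adjusted p = 1.99e-12, and adjusted p = 0.281 with an estimated correlation), with Uqcr10 up by 2.03 and Atp5l by 1.85. Cox7c and Ndufs1 were lower, Cox7c at least 5.37-fold. The Cox7c probe set had an s suffix, for sequences shared with others, and read 7.43 in unbound RNA and 2.04 on every IP array. Whether it reads the main Cox7c transcript was not tested. The oxidative phosphorylation median lay at the 76.3th percentile of matched lists, and quantile normalisation and the poly-A scaling each ended its camera call. Counts were 62 higher and 1 lower with the median over all probe sets, 52 and 1 with that over expressed ones and 0 and 72 with the poly-A scaling.

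The neighbours of Slc6a4 in the genome did not move together. Nsrp1 rose by 2.21 (97.9th percentile of all tested genes) and Blmh by 1.09 (90.7th percentile), while Cpd (-1.63) and Gosr1 (-1.05) fell. The list had a median of 0.02 (camera, adjusted p = 0.241). Blmh fell under the 2-fold limit with quantile normalisation (0.99), and Cpd with both median scalings (-0.60 and -0.82). Gosr1 lost its call without scaling, with quantile normalisation and with both medians. Either median thus left 2 neighbours higher and 0 lower, and the poly-A scaling 0 and 3.

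**Figure D3:**
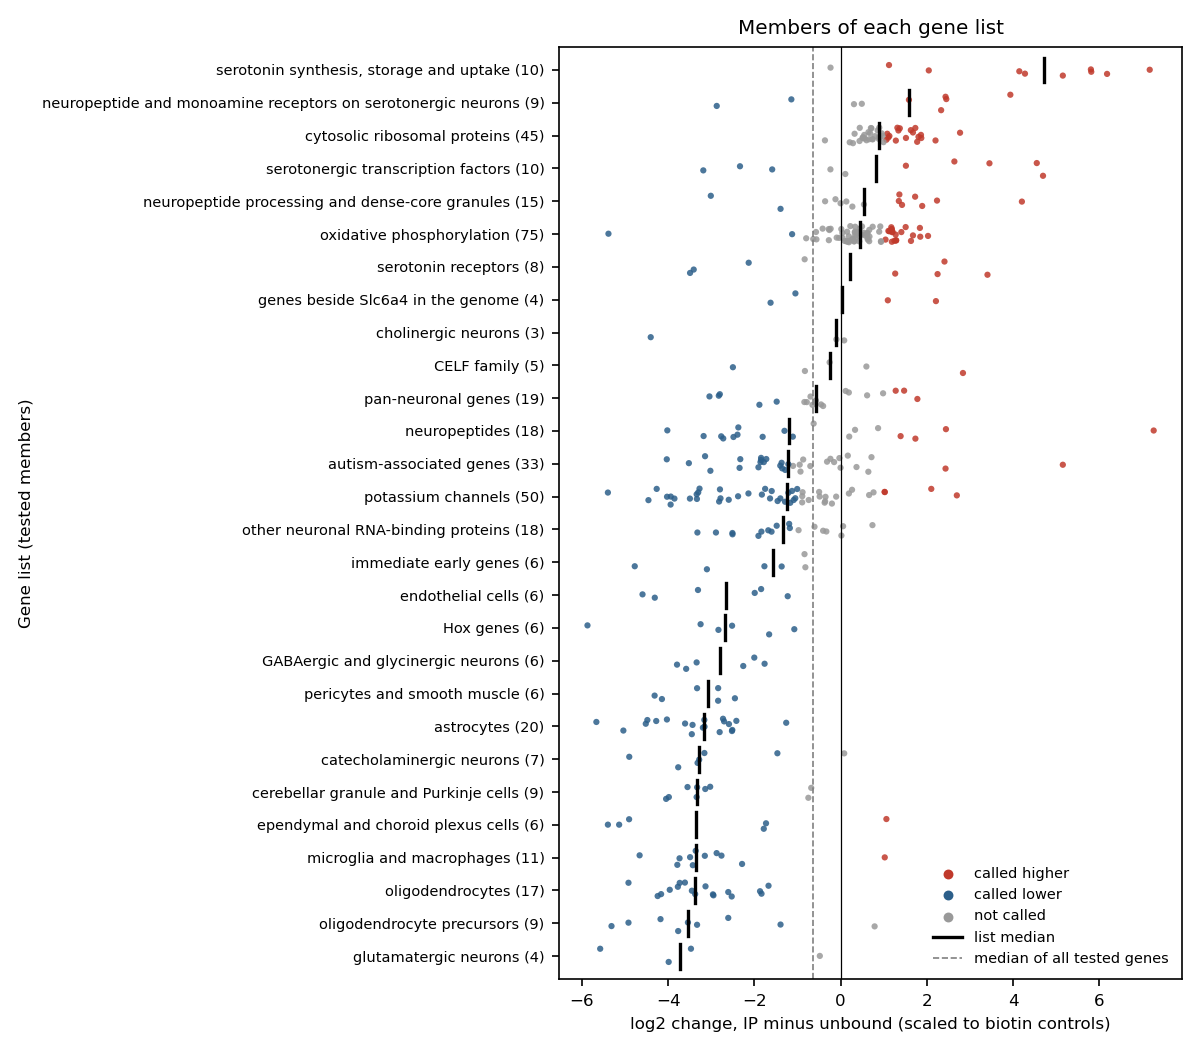
Log2 change, IP minus unbound, of each tested member (point) of 28 gene lists, with the list median as a black bar, members called higher in red and lower in blue, and the median of all tested genes (-0.65) as a dashed line. The serotonin synthesis list has the highest median (4.71) and the glutamatergic list the lowest (-3.73), under the scaling to the biotin controls.

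Of the 28 lists tested, 6 were higher and 7 lower than other genes by camera with its preset correlation, and none passed with an estimated correlation. Within each list the same number of genes was called when p-values were adjusted over the list alone. Apart from that test, only serotonin synthesis and ribosomal proteins kept their camera call under every alternative.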

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

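The splits of the arrays and the tests on calls under quantile normalisation, on groups of genes by span, on the scaling of the ribosomal protein genes and on the poly-A controls were chosen after the results were seen, and those on span-matched lists and on shared probe sets of ribosomal protein genes before.

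Poly-A spike controls, bacterial RNAs added to a sample before amplification, lie outside the comparison of genes and were far higher in IP. Their 24 probe sets were 2.91 higher on the log2 scale (7.52-fold, range 1.82 to 4.16), and 24 of 24 were higher in IP. Brighter IP arrays are argued against, because the biotin controls added at hybridisation differed by only 0.23. Shorter amplified products in the unbound samples are argued against as the whole cause, because the probe sets at the 3 prime end still differed by 2.57. More spiked RNA per unit of sample mRNA in IP may be the cause and cannot be told apart from a different amount spiked, because the amounts per sample are not given in the sources used here. Scaled to these controls, chosen after the data had been seen, 9992 genes were lower and 35 higher in IP, and 624 of the 1104 genes called higher became lower, so the direction of many called changes rests on which controls are taken.

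Probe sets without a single gene symbol were outside the gene comparison. Of 10092 such probe sets, 1648 passed the detection limit, 222 were higher in IP and 801 lower, with a median log2 change of -0.91.

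Lower genes outnumbered higher genes in IP by 4354 to 1104. Quantile normalisation gave 49.7% lower, but it sets both groups to the same distribution and so evens the calls by construction, and how much the scaling between groups contributes cannot be told apart. Genomic span is a candidate explanation for part of it: the share of lower calls was 51.8% in the shortest of 4 equal groups of genes by span, then 77.8%, 89.3% and 93.7% in the longest, with Spearman's rho of -0.33 between span and log2 change across genes, which are not independent replicates. The loss of transcripts of all other cell types from the IP, a biological explanation, was not separated from these and stays open. So does the difference between ribosome-bound and unbound RNA, which the design confounds with cell type.

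Ribosomal protein genes were higher in 18 of 45 cases. Probe sets shared with related sequences are argued against, because the 28 members read by probe sets without a cross-hybridisation suffix had a median of 1.61 above all genes, against 1.54 for the list. How much the scaling between groups contributes cannot be told apart: the median above all genes was 0.61 at its lowest over 6 scalings (quantile normalisation), but a scaling that shifts all genes alike hardly moves it, and the calls went from 44 higher with either median to 38 lower with the poly-A scaling. Short genes of similar mean level may account for it, because the list's median lay at the 95.5th percentile of lists matched on span and level, within their central range. That median, 0.89, was still above the 0.57 of the matched lists. Span and level were matched together, so the share of span alone was not tested. A biological enrichment of these mRNAs in serotonin neurons stays open and untested.

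For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split, 1 of the 10, gave 1104 higher genes where the highest other split gave 0, 4354 lower genes where the highest other gave 0, and 13 called lists where the highest other gave 11. The other splits mix IP and unbound arrays in each group and keep part of the difference between them. The rest widens the spread within groups, which works against calls of genes. Their 0 called genes are therefore no measure of chance, and no conclusion is drawn from the contrast. The other splits that part all 3 pairs, as the real split does, called 6 to 9 lists.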

How the results depend on the processing

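The scalings by poly-A controls and by the median over expressed probe sets, the spread from the unbound arrays alone and the removal of genes with identical replicate values were chosen after the results were seen.

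The log2 change of Slc6a4 kept its direction and call under all alternatives, from 2.47 (poly-A scaling) to 6.17 (median over all probe sets), and Celf6 under all but the poly-A scaling, where it was 0.16 (adjusted p = 0.253, against 0.00169 or less and 2.74 to 3.86 elsewhere). Leaving out each array or pair in turn gave 1087 to 1127 higher genes, 4179 to 4405 lower genes, 10 to 15 called lists, and 5.05 to 5.24 for Slc6a4 and 2.74 to 2.95 for Celf6.

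The count of higher genes was 3563 with the median over all probe sets, 2887 with the median over expressed ones, 2507 with quantile normalisation, 2330 with no fold threshold, 275 at 4-fold or more and 35 with the poly-A scaling. The count of lower genes was 2067, 2481, 2479 and 2268 with both medians, quantile normalisation and 4-fold, and 9992 with the poly-A scaling. The changed fold limits and shifted levels account for these by construction. With the poly-A scaling 624 of the 1104 higher genes became lower. The spread from the unbound arrays alone gave 1103 higher and 4351 lower genes.

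Lists called by camera fell from 13 to 8 with no filter, 7 with the filter at log2 7 and 8 with the mean of all probe sets. They fell to 7 without genes of identical values and 0 with an estimated correlation. That last test also ended calls of lists with a negative estimate, microglia (-0.04) and receptors on serotonergic neurons (-0.09). Called lists rose to 19 with each array's own biotin controls and with every probe set by itself. The latter counts a gene with several probe sets several times. The causes were not tested further. Fry, which asks only whether a list's genes move on balance and compares them with no other genes, passed 27.

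The poly-A scaling reversed the sign of Atp5l (-0.83), Blmh (-1.58), Celf5 (-2.08), Maoa (-1.56), Nsrp1 (-0.47), Pts (-0.63), Rpl19 (-0.81), Rps10 (-0.48), Scg2 (-0.44) and Uqcr10 (-0.65), by the constant it subtracts. The median over all probe sets reversed Celf1 (0.19), Celf4 (0.77) and Qdpr (0.79), and that over expressed probe sets reversed Celf4 (0.55) and Qdpr (0.57). Over named genes and all alternatives, 2600 values kept direction and call, 11 gained a call, 16 lost it and 15 reversed. Pts (0.90) and Blmh (0.99) lost the 2-fold limit with the mean of all probe sets. Celf1 gained a call by another probe set (-1.75) and without replicate 2 (-1.02).

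Only lists not called in either setting reversed camera direction. Medians above all genes (in brackets) changed sign only for CELF and pan-neuronal genes. Neuropeptides turned down unscaled (-0.57), with the median over all (-0.28) or expressed probe sets (-0.50), the filter at log2 7 (-0.57) and the mean of probe sets (-0.65). CELF genes turned down with quantile normalisation (-0.42) and every probe set (-0.27), and pan-neuronal genes with the former (-0.60). With no filter, autism-associated (-0.77) and immediate early genes (-0.57) turned up, the former also with poly-A scaling (-0.59). Cholinergic genes turned up without IP replicate 1 (0.53), unbound replicate 2 (0.71), replicate 1 (0.46) or replicate 2 (0.67). All leave-outs gave 0.43 to 0.71. The cause was not tested. Over all lists 555 values kept direction and call, 39 gained a call and 58 lost it. Without IP replicate 1, oligodendrocyte precursors (adjusted p = 0.0595), cerebellar genes (0.0595) and potassium channels (0.0648) lost their call. Without unbound replicate 1, serotonergic transcription factors (0.0554) and cerebellar genes (0.0777) did, and without unbound replicate 2, oligodendrocyte precursors (0.0609). Without both arrays of replicate 1, precursors (0.0790), cerebellar genes (0.103) and potassium channels (0.0707) did. A call was gained by GABAergic genes without IP replicate 1 (0.0465) and Hox genes without unbound replicate 1 (0.0444) or 3 (0.0452). Endothelial genes gained 1 without unbound replicate 3 (0.0452) or both arrays of replicate 3 (0.0488).

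With the replicate pairs as a block 1108 genes were higher and 4360 lower, and the GABAergic and Hox lists (adjusted p = 0.0484 for both) gained a call. Adjusted p with the block was larger, 2.78e-05 for Slc6a4 and 5.52e-05 for Celf6 (limma). The block changed no other call of a named gene or list.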

Other observations

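The lists below were put together after the largest changes had been seen, so they describe these arrays and test nothing independently.

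Several long noncoding RNAs described as nuclear were low in IP. Neat1 (-4.73), Meg3 (-4.42), Miat (-4.34) and Malat1 (-3.46) fell, Malat1 from 15.02 in unbound RNA to 11.56 in IP. Of 8 tested, 7 were lower and none higher, and the same 7 and 0 were counted without scaling and under quantile normalisation and both median scalings. ND5, the mitochondrially encoded gene tested, fell by 4.32.

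Host transcripts of small nucleolar RNAs moved both ways. Zfas1 rose by 3.49 and Snhg4 by 3.23, with Snhg6, Snhg7, Snhg8 and Snhg12, while Snhg11 (-3.40), Snhg14 (-4.09) and Rian (-3.59), counted above among the nuclear RNAs, fell. The list without those genes had 6 higher and 0 lower of 9 (0 and 5 under the poly-A scaling). Of 16 translation factors and other mRNAs with a terminal oligopyrimidine tract, Fau, Naca and Eif3f were higher and Pabpc1 lower (median 0.43, and -2.25 under the poly-A scaling). Counts were 14 higher and 0 lower with the median over all probe sets and 12 and 0 with that over expressed ones, where Pabpc1 lost its call. Under the poly-A scaling 0 were higher and 15 lower.

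Bex4 rose by 3.78 and Armcx6 by 3.39, and 5 of 15 genes of the Bex, Tceal and Armcx family were higher and none lower (median 0.39, and -2.29 under the poly-A scaling). Counts were 12 higher and 0 lower of 16 with the median over all probe sets, and 1 and 12 of 15 with the poly-A scaling. Imprinted genes moved both ways: Asb4, Calcr, Dlk1, Mest and Blcap were higher, and Cdkn1c, Dcn, Plagl1, Igf2r, Meg3, Rian and Snhg14 were lower. The list without the last 3 had 5 higher and 4 lower of 22, against 13 and 4 with the median over all probe sets and 0 and 19 with the poly-A scaling.

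In the order of genes along the chromosome, Timm22 and Ankrd13b near Slc6a4 were also higher, by 1.34 and 1.01, and Ssh2 and Git1 were lower, at -1.99 and -1.42.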
